A study of Arabidopsis thaliana with 12 samples.

How the data were processed

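RNA came from Arabidopsis seedlings that had spent 7 days on MS plates (0.5 strength, 1% sucrose) at 22 °C, taken either from there or following 1 h at 37 °C. The lines were the accessions Col-0 and Ws and the mutant QK. Biotin-labelled cRNA was hybridised to Affymetrix arrays, 2 per group and 12 in all. The values deposited by the authors are signal intensity on a linear scale, 1 value per probe set and array. The submitters name GCOS 1.4 for the processing. The summary algorithm, the scaling target and the detection calls are not stated and were not used here. The array medians of 75.6 to 87.3 lay so close together that no further normalization was applied.

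The table held 18465 probe sets. The annotation used paired 10396 of them with exactly 1 gene and 398 with several, and listed no gene for 7671. Of the single-gene probe sets 10340 matched a gene of the reference table, assembly TAIR10.1. The table was used for names and for the order of neighbouring genes, since the deposited values name no genome build. Genes were named only from probe sets with exactly 1 gene. Signals were transformed as log2(signal + 16). A probe set was tested if it lay above the 35th percentile of its array in at least 2 arrays, which left 13631, of which 7294 had exactly 1 gene. No Affymetrix control probe sets were in the table (0), so the planned scaling on hybridisation controls was not run.

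Groups follow the sample labels. Models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and empirical Bayes variances that follow a mean trend. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 13631 probe sets of a contrast. A probe set was called at an adjusted p under 0.05 and a change of at least 2-fold. Folds printed are of the signal plus 16. The contrasts were heat against control in each line, the QK heat response minus the mean of both wild-type responses, QK against each wild type at control and at heat, and Ws against Col-0. "Higher than both" means called against each wild type with the same sign. The 12-array fit had 6 residual degrees of freedom and the 10-array fit, which leaves out both arrays labelled Col-0 replicate 2 and was chosen after the data were seen, had 4.

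Before the data were examined, 22 gene lists with 353 genes were fixed, of which 52 genes had a tested single-gene probe set, and the 8 lists with at least 3 such genes were tested. A further 3 lists, for the mitochondrial genome, the plastid genome and late embryogenesis abundant proteins, were added after the data were seen. Lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, adjusted over the lists in a contrast. In the 12-array fit 13 of 48 tests of the fixed lists passed with the preset correlation and 0 with the estimated one. A gene with several probe sets took the brightest one. The named genes were fixed by a rule before the data were examined. It takes the 6 highest and 6 lowest called genes of each heat contrast and of the QK response, and the 5 highest and 5 lowest of each comparison of levels, if all pairs of arrays show the same sign. It adds from each list up to 3 members that rose and 3 that fell, or 2 values where none was called. The rule was applied to the 10-array fit as well. The class A1 heat shock factors had 0 of 4 genes with a single-gene probe set in the tables used and are not analysed here.

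Whether the replicate numbers pair the arrays was checked by correlating, across probe sets, the differences between replicates 2 and 1 of each pair of groups. In 14 of 15 pairs the correlation was above 0.1, and it was -0.173 for both Col-0 groups. Among the Ws and QK groups it was 0.587 to 0.807 in 6 of 6. The model planned before did not use the replicate number, and the fits with it as a block are given as alternatives.

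The pipeline was tested on simulated data, with 100 probe sets changed 4-fold and 100 changed 16-fold in heated Ws. Noise was drawn independently for each array with the spread of the 10-array fit. The simulation thus held no replicate effect and no pair against its labels, and its recovery does not describe the real 12-array fit. The 12-array fit recovered 85% and 97% and made 10 false calls, and the 10-array fit recovered 86% and 98% and made 5. In Col-0, left unchanged, there were 0 false calls. A photosynthesis list lowered by 1 log2 unit in heated QK was recovered at -0.99 and -1.00.

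Alternatives tried were the replicate block, quantile normalization, centring on the 75th percentile, pseudocounts of 1 and 64, no filter on dim probe sets, a filter at the 50th percentile, no variance trend, no fold threshold, a minimum of 4-fold, a fit to the 4 arrays of 1 genotype, each wild type alone, and leaving out each array in turn.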

Results

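RNA levels were measured with 12 Affymetrix arrays, 1 per pool of Arabidopsis thaliana seedlings. The seedlings were 7 days old and came from the accessions Col-0 and Ws and from the line QK. QK is known from the literature as a quadruple knockout of the class A1 heat shock factors, the transcription factors that start the heat shock response, and carries mutant alleles from both accessions. Each line was sampled at 22 °C (control) and after 1 h at 37 °C (heat), with 2 biological replicates per group, so that the 12 arrays form 6 groups. The design asks how heat changes RNA levels in each line and how far the response of QK differs from that of the wild types. The array medians lay between 75.6 and 87.3 signal units, and the highest signal of any array was 18418. The precision of every value below is limited by the number of arrays, 2 per group. The genes that QK lacks are not analysed here.

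The 2 arrays labelled Col-0 replicate 2 stood against their treatment labels. All 62 probe sets raised at least 4-fold by heat in both Ws and QK were brighter in the array labelled Col-0 control replicate 2 than in the array labelled Col-0 heat replicate 2, and all 11 lowered probe sets were dimmer. HSP17.6C, a cytosolic small heat shock protein, had a signal of 11977.2 in the array labelled control replicate 2 and 11.7 in the array labelled heat replicate 2, against 12.8 and 11501.6 in the arrays labelled control and heat replicate 1. The heat index, the median log2 level of those raised probe sets minus that of the lowered ones, was 3.09 in the array labelled Col-0 control replicate 2 and -3.45 in the array labelled Col-0 heat replicate 2. It lay between -4.22 and -3.42 in the other control arrays and above 2 in the other heat arrays, up to 3.07. Across probe sets, the correlation of the Col-0 arrays with their own replicate was 0.812 at control and 0.808 at heat, and 0.919 to 0.938 in Ws and QK. The groups were kept as labelled. Counts and list tests are therefore given with all 12 arrays, as planned, and with the 10 arrays left without this pair, a choice made after the data were seen. In the 10-array fit each Col-0 group holds 1 array, assumed to vary like the arrays of the other groups.

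**Figure D1:**
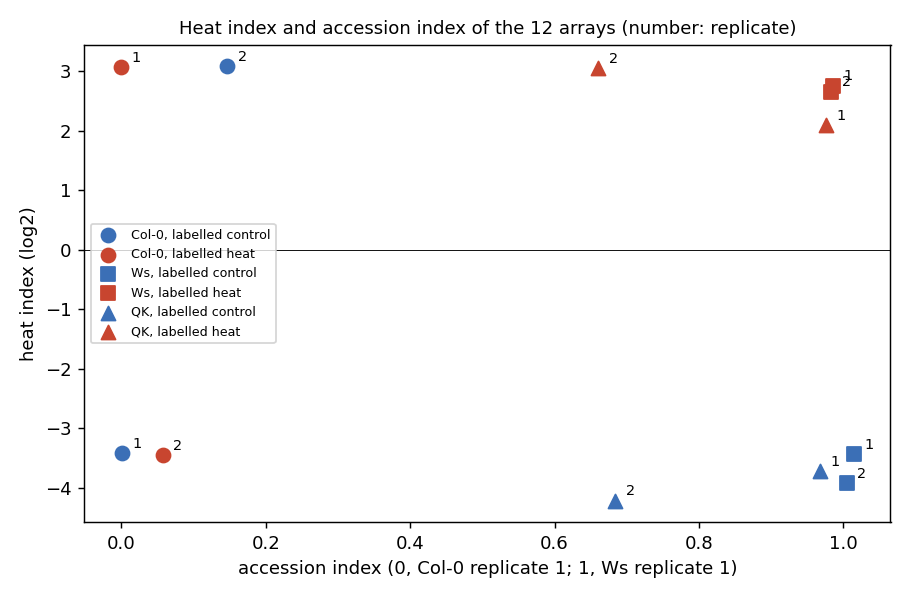
Heat index (log2) of each array against its accession index, on which Col-0 replicate 1 lies near 0 and Ws near 1, coloured by the labelled treatment. The array labelled Col-0 control replicate 2 lies at 3.09 on the heat index and the array labelled Col-0 heat replicate 2 at -3.45, and both lie near Col-0 on the accession index (0.146 and 0.0570).

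Heat raised genes of the protein-folding machinery in Ws. Of the 8 measured small heat shock proteins, chaperones that keep unfolding proteins soluble, 7 rose in Ws in the 10-array fit. HSP17.6C rose by log2 8.53, from a signal of 13.2 ± 0.919 to 10892 ± 2299.8 (SD, n = 2), and HSP26.5, an organelle member, rose by log2 7.76, from 16.9 ± 9.55 to 6953 ± 100 (SD, n = 2). With control signals this low the size of the change depends on the 16 added before the logarithm. Of 7 co-chaperones, 5 rose, among them HOP3, which links HSP70 to HSP90 (log2 change 6.11), FES1A, an HSP70 partner (5.90), and HSA32, needed to keep acquired heat tolerance (4.42). The cytosolic HSP70 genes HSC70-2 and HSC70-3 rose by log2 2.69 and 2.94. In Col-0, with 1 array per arm, HSP26.5 rose by log2 8.09, HSP23.5, a mitochondrial member, by 7.32, HOP3 by 6.87 and AT1G71000, a J-domain protein, by 7.29.

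In the 10-array fit heat raised 471 and lowered 276 of 13631 probe sets in Ws, and raised 217 and lowered 58 in Col-0. HSP26.5 in Ws had a standard error of 0.64 and an adjusted p of 0.00148, and HSP17.6C a standard error of 1.35 and an adjusted p of 0.0163. Adjusted over the list alone, 7 small heat shock proteins and 5 co-chaperones were called in each accession, against 4 and 5 in Col-0 over all probe sets. With camera and the preset correlation the small heat shock proteins were higher as a set in Ws (mean log2 6.49, adjusted p = 4.5e-09) and Col-0 (6.76, adjusted p = 8.1e-12), and with an estimated correlation adjusted p = 0.147 in both. The co-chaperones gave mean log2 3.67 in Ws (adjusted p = 1.5e-08) and 3.96 in Col-0 (adjusted p = 1.7e-09), with adjusted p = 0.127 and adjusted p = 0.104 with an estimated correlation. Over all 12 arrays the Ws sets kept their means (camera adjusted p = 2.2e-05 and adjusted p = 4.6e-05, and adjusted p = 0.318 for both with an estimated correlation), while in Col-0 the means were 0.18 and 0.31 and neither set was called (adjusted p = 0.566 and adjusted p = 0.721). In the 12-array fit limma called 8 probe sets raised and 0 lowered in Ws, with 1711 at an unadjusted p under 0.05, and 0 raised and 0 lowered in Col-0, with 8 at an unadjusted p under 0.05. HSP26.5 in Ws then had an adjusted p of 0.38 at the same log2 7.76. With the replicate number as a block, the 10-array counts were 549 and 570 in Ws and 392 and 444 in Col-0. The raised count of Ws lay between 258 and 453 and the lowered count between 29 and 258 as each Ws or QK array was left out, the lowest both times without Ws heat replicate 1. In Col-0 the raised count then lay between 161 and 185 and the lowered count between 6 and 22.

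**Figure D2:**
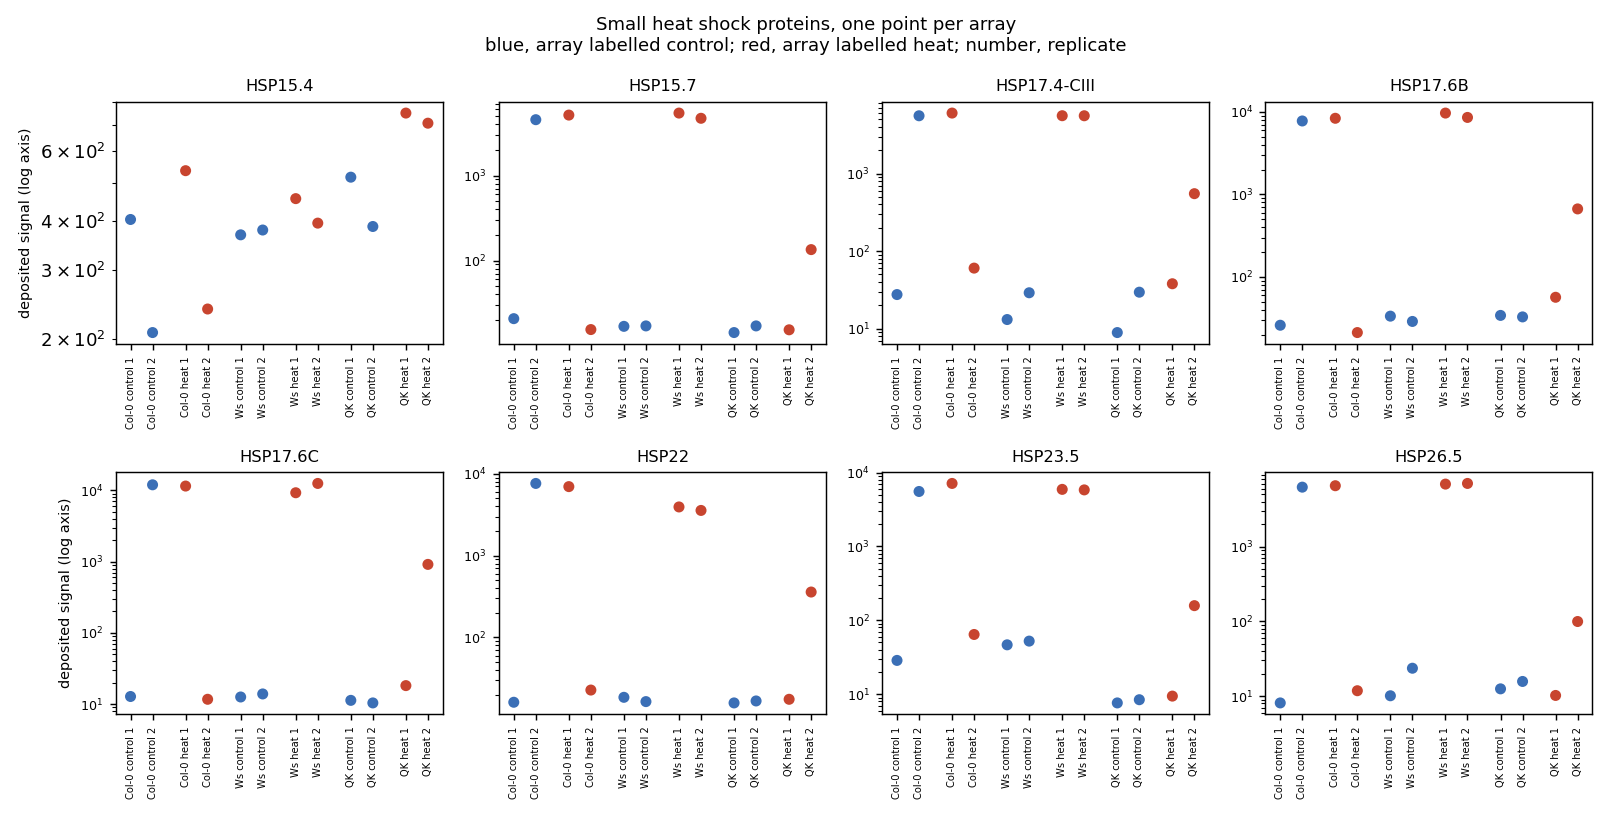
Deposited signal (log axis) of the measured small heat shock protein genes in each array, by labelled group (blue, control; red, heat). HSP17.6C reached 10892 on average in heated Ws and 18.2 and 914.7 in the QK heat arrays, and the pair labelled Col-0 replicate 2 stands against its labels.

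Among the genes lowered by heat in the 10-array fit AT4G13580, of the dirigent family, fell by 2.60 on the log2 scale in Ws (SE 0.24, adjusted p = 0.00211) and by 2.53 in Col-0 (SE 0.34, adjusted p = 0.0198). AT4G32460, a cell wall protein of the DUF642 family, fell by 2.51 in Ws and by 2.44 in Col-0. SBT4.12, a subtilisin-like protease, fell by 2.27 in Ws. PYK10, the root and hypocotyl beta-glucosidase of the ER bodies, fell by 1.44 in Ws, and of the 3 root markers it was the single member called, against 3 when adjusted over the list alone. The root markers were lower as a set in Ws (mean log2 -1.18, camera adjusted p = 0.0142), with adjusted p = 0.147 with an estimated correlation, and with 12 arrays adjusted p = 0.0123 and adjusted p = 0.318. None of the 7 photosynthesis genes was called by limma. Their mean change in Ws was -0.39, with a camera adjusted p of 0.0281 and adjusted p = 0.205 with an estimated correlation, and with 12 arrays adjusted p = 0.0123 and adjusted p = 0.367.

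The highest genes called in Ws with all 12 arrays were AT1G50110, an aminotransferase (log2 change 3.78), AT4G27890, an HSP20-like protein (3.03), AT5G55640 (2.79) and AT2G32760 (2.30). Their changes were smaller than those of HSP26.5 or HSP17.6C, which were not called in that fit. The pair labelled Col-0 replicate 2 widens the spread of genes that respond in Col-0, so this fit favours genes without a response there. AT1G50110 went from 46.1 ± 8.63 to 840 ± 129 in Ws (SD, n = 2), and lay between 54.9 and 78.5 in all 4 Col-0 arrays, which holds whatever their treatment labels. At heat it was higher in Ws than in Col-0 by log2 3.40 (SE 0.29, adjusted p = 0.00293), and AT4G27890 by 3.18 (SE 0.21, adjusted p = 0.00103). The difference in heat response between Ws and Col-0 itself missed the threshold, with adjusted p = 0.0548 for AT1G50110 and AT4G27890 and 0 probe sets called by limma in either fit (432 at an unadjusted p under 0.05 with 12 arrays and 156 with 10). With the replicate number as a block the 12-array fit called 5, among them AT1G50110, AT4G27890 and AT5G55640 (adjusted p = 0.0451 for each), and the 10-array fit called 0 by limma (415 at an unadjusted p under 0.05).

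In QK heat replicates 1 and 2 the 7 small heat shock proteins that rose in Ws lay far below their signal in the Ws heat arrays and in Col-0 heat replicate 1. They were higher in QK heat replicate 2 than in the array labelled Col-0 heat replicate 2, as HSP26.5 with 99.6 and 11.8. The eighth, HSP15.4, had 750.9 and 707.7 in the QK heat arrays and 455.0 and 394.2 in those of Ws. HSP17.6C had a signal of 18.2 in QK heat replicate 1 and 914.7 in QK heat replicate 2, and 0 of the 8 genes were called in the 10-array fit (camera mean log2 1.65, adjusted p = 0.00616, and adjusted p = 0.352 with an estimated correlation). With 12 arrays the set was not called (adjusted p = 0.174). Among probe sets with a single gene, the 3 largest log2 changes called in QK in the 10-array fit were at nad6 and nad5 of the mitochondrial genome, which encodes subunits of the respiratory chain. Some had control signals so low that the size of the change depends on the 16 added. With all 12 arrays limma called 0 of the 14 genes over all probe sets. The probe set for nad6, a complex I subunit, rose from 11.2 ± 3.04 to 1677 ± 36.9 (SD, n = 2), a log2 change of 5.96 (SE 0.16, adjusted p = 0.000119), and cox2, a complex IV subunit, rose by log2 4.18 (SE 0.19, adjusted p = 0.000591). Of 14 mitochondrial genes 11 rose in QK, 11 in Ws and 10 in Col-0 in the 10-array fit, with mean log2 changes of 3.26, 2.80 and 2.82. This list was added after the data were seen, and in the 10-array fit its camera call passed with an estimated correlation in QK, Ws and Col-0 (adjusted p = 0.0302, adjusted p = 0.0476 and adjusted p = 0.0292). That call was lost with the replicate number as a block (adjusted p = 0.169, adjusted p = 0.139 and adjusted p = 0.121) and with all 12 arrays (adjusted p = 0.295, adjusted p = 0.328 and adjusted p = 0.99). The assignment is uncertain, since near-copies of these genes lie in the nuclear genome, as with AT2G07722 and AT2G07741, which rose in QK by log2 4.75 and 4.40.

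**Figure D3:**
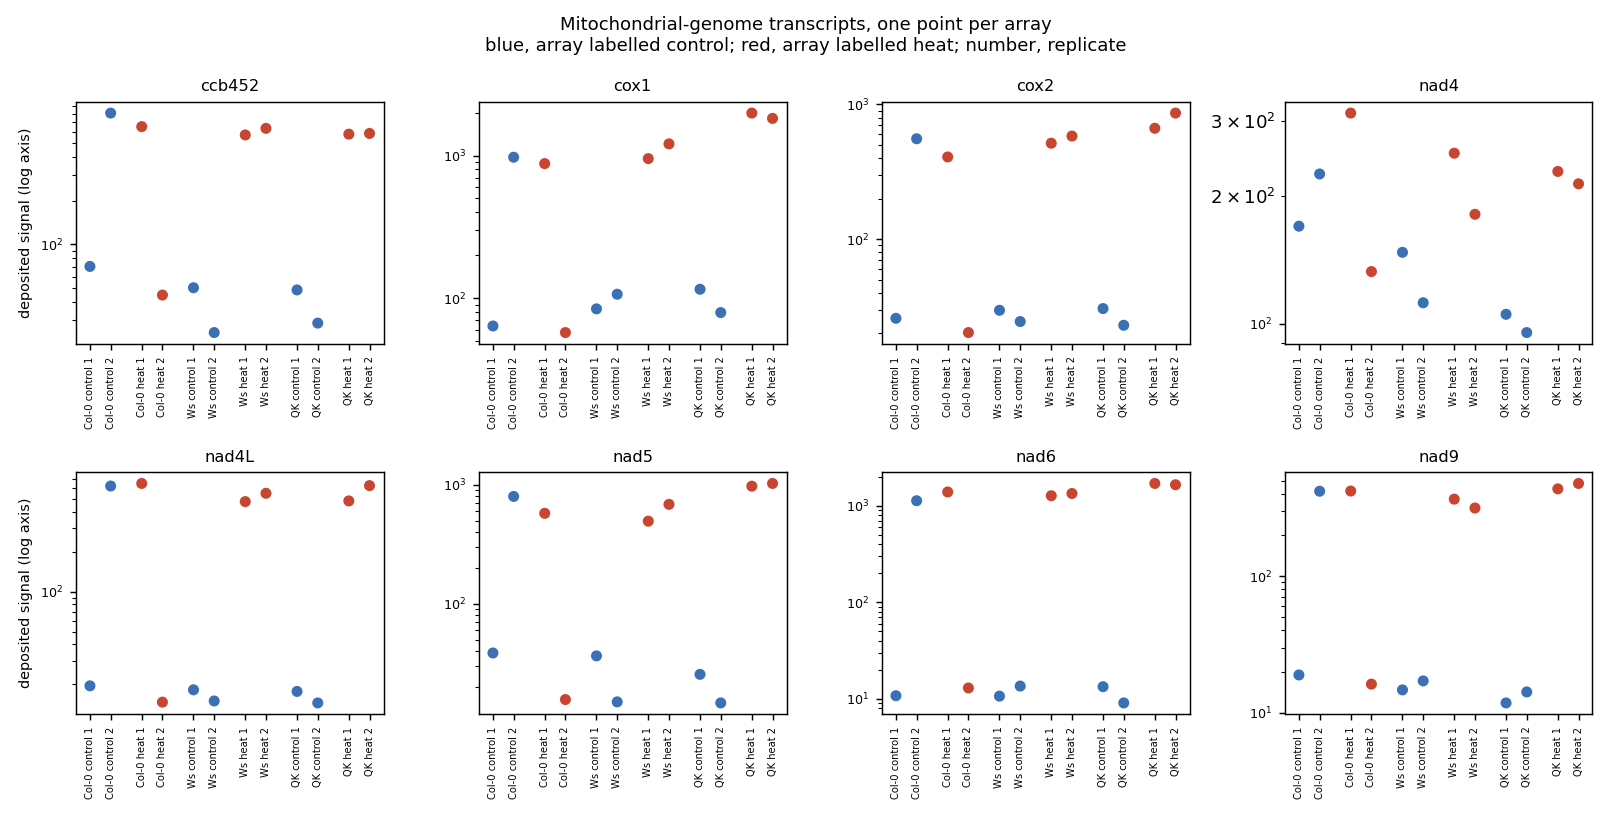
Deposited signal (log axis) of probe sets for 8 mitochondrial genes in each array, by labelled group (blue, control; red, heat). The nad6 probe set averaged 1305 in heated Ws and 1677 in heated QK, against 12.2 and 11.2 at control.

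Heated QK seedlings also raised genes of protein folding in the endoplasmic reticulum. CRT1B, a calreticulin, rose 6.75-fold, from 895 ± 530 to 5727 ± 1769 (SD, n = 2), and ERDJ3B, a J-domain co-chaperone of that compartment, rose 4.29-fold in the 10-array fit. These are 2 of 3 measured members, also when adjusted over the list alone, and the set gave mean log2 1.66 (camera adjusted p = 0.0131, and adjusted p = 0.284 with an estimated correlation; with 12 arrays adjusted p = 0.00176 and adjusted p = 0.166). Of 4 auxin genes, GH3.3, which conjugates auxin to amino acids, rose by log2 2.03. With 12 arrays the set gave camera adjusted p = 0.00934, and adjusted p = 0.212 with an estimated correlation. In the 10-array fit the set call was lost with the replicate block and with an estimated correlation. The highest named genes with all 12 arrays were AT4G34630 (log2 3.65, adjusted p = 0.044), AT4G29520 (3.08), AT3G16330 (2.56), AT5G44060 (2.28) and XTH33, a cell wall xyloglucan enzyme (2.24). Among the lowered genes of the 10-array fit, the log2 change was -3.03 for AT5G54370, -2.86 for AT4G13580, -2.73 for AT4G32460 and -2.59 for SBT4.12. The root markers gave a mean of -0.97. With 12 arrays camera gave adjusted p = 0.0302, adjusted p = 0.385 with an estimated correlation and adjusted p = 0.0689 with the replicate block, and limma called 0 members.

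Heat raised 160 and lowered 189 probe sets in QK in the 10-array fit (273 and 451 with the replicate block), and 34 and 1 with all 12 arrays. Of the raised probe sets 82 were also raised in Ws, where 5.53 would be shared by chance, and of the lowered ones 129, where 3.83 would be shared by chance. The raised count lay between 55 and 138 and the lowered count between 8 and 132 as each Ws or QK array was left out, both lowest without QK heat replicate 2.

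In the 10-array fit the log2 difference in response was -7.05 for HSP26.5 (SE 0.85, adjusted p = 0.0187), -6.73 for the J-domain gene AT1G71000 and -6.09 for HSP15.7, a peroxisomal small heat shock protein. It was -5.60 for HOP3, -5.68 for AT1G21550, an EF-hand protein, and -5.15 for AT5G25450. HSC70-2 differed by -2.61 (SE 0.33, adjusted p = 0.0225). HSP26.5 reached 6953 ± 100 in heated Ws and 54.9 ± 63.2 in heated QK (SD, n = 2). Of the 8 small heat shock proteins 2 had a lower response in QK over all probe sets and 7 when adjusted over the list alone. Of the 7 co-chaperones the counts were 4 and 5. As sets their mean differences were -4.97 (camera adjusted p = 5.0e-11) and -3.05 (camera adjusted p = 3.3e-11), with adjusted p = 0.171 and adjusted p = 0.0727 with an estimated correlation. The planned 12-array test called neither set, with means of -1.68 (camera adjusted p = 0.207) and -1.22 (camera adjusted p = 0.188). In that fit the Col-0 means were 0.18 and 0.31, against 6.76 and 3.96 without the pair labelled Col-0 replicate 2. The pair thus lowers the wild-type response that QK is set against, and this test cannot decide on QK.

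A smaller group of genes responded more in QK than in the wild types in the 10-array fit. XTH33 did so by log2 2.58 (SE 0.39, adjusted p = 0.0369), AT4G37240 by 2.47, AT5G44060 by 2.41, AT4G35940 by 2.35, UGT76B1, a glycosyltransferase that acts on a defence signal, by 2.29, and AT3G16330 by 1.98. UGT76B1 went from 160 ± 6.22 to 758 ± 169 in QK and from 94.4 ± 18.8 to 76.2 ± 7.78 in Ws (SD, n = 2). The endoplasmic reticulum genes had a mean difference of 1.55 (camera adjusted p = 0.00156, and adjusted p = 0.178 with an estimated correlation), with 0 members called by limma and 2 when adjusted over the list alone. The auxin genes had a mean difference of 1.06 (camera adjusted p = 0.0103, and adjusted p = 0.244 with an estimated correlation), with GH3.3 called (log2 1.83). With 12 arrays these sets gave camera adjusted p = 2.4e-05 and adjusted p = 0.000598, and adjusted p = 0.0613 and adjusted p = 0.0966 with an estimated correlation. Limma then called 0 endoplasmic reticulum members over all probe sets, and 1 with the replicate block. The mitochondrial genes differed by a mean of 0.45, and by 1.93 with 12 arrays, where limma called 0 (camera adjusted p = 2.3e-06, and adjusted p = 0.461 with an estimated correlation). The larger value comes with the pair labelled Col-0 replicate 2. With that pair the mean change in Col-0 was -0.14, and without it 2.82, so 1.93 does not measure a difference of QK.

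The 10-array fit called 159 probe sets with a lower and 21 with a higher response in QK (280 and 95 with the replicate block). In the 12-array fit limma called 0 with a lower and 1 with a higher response, with 410 at an unadjusted p under 0.05. The latter was the probe set 247165_at, which has no gene in the annotation used (log2 2.33). The pair labelled Col-0 replicate 2 enters the 12-array fit, where it shrinks the Col-0 response and widens the spread. The lower count lay between 58 and 123 and the higher count between 2 and 11 as each Ws or QK array was left out, both lowest without QK control replicate 1. Of 228 probe sets raised at least 4-fold between the arrays labelled Col-0 replicate 1, the median log2 change was 3.39 in Ws and 0.55 in QK, and the change was lower in QK than in Ws for 78.5%. Of 47 lowered at least 4-fold in the same pair, the medians were -1.91 in Ws and -1.65 in QK.

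**Figure D4:**
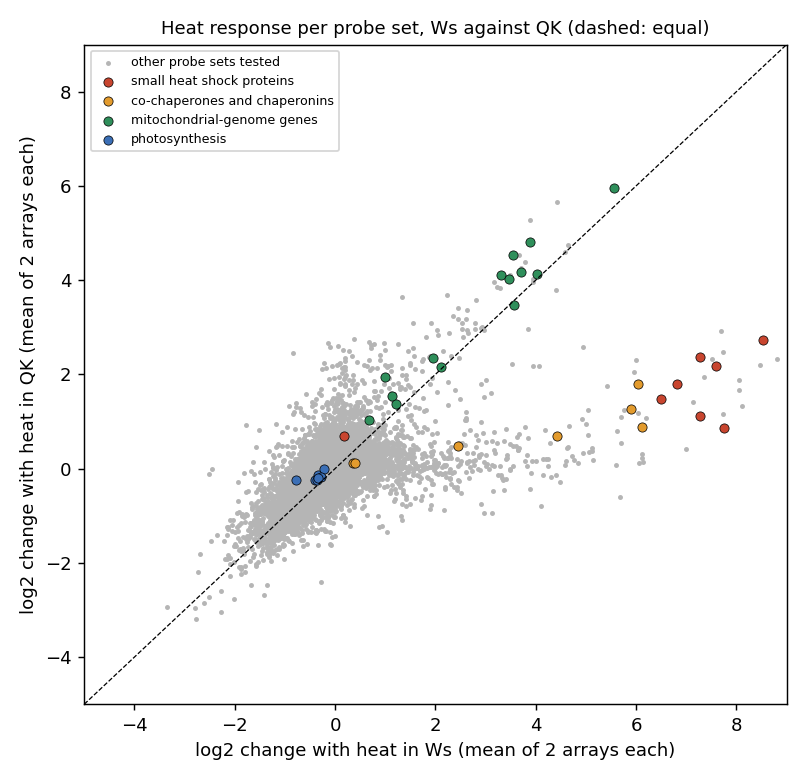
Log2 change on heat in Ws (horizontal) against that in QK (vertical), each point a tested probe set, from the fitted group means. The chaperone genes such as HSP26.5 lie at 7.76 in Ws and 0.87 in QK, and the mitochondrial probe sets such as nad6 lie at 5.55 and 5.96.

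QK seedlings carried RNAs that were low in both wild types, at control as well as at heat. BGLU19, a beta-glucosidase, was at 1520.5 ± 1088 in QK and 18.6 ± 3.68 in Ws at control (SD, n = 2), and between 11.4 and 60.8 in the 4 Col-0 arrays. AT3G17520 and LEA18, late embryogenesis abundant proteins that accumulate in maturing seeds, were higher in QK than in Ws at control by log2 5.01 and 4.47. ICL, the isocitrate lyase of the glyoxylate cycle that turns seed oil into sugar, was higher in QK than in Ws by log2 3.92 and AT1G04560 by 3.80 with all 12 arrays. DELTA-VPE, a processing protease of the seed coat, and PDF1.4, a defensin-like protein, were higher by at least log2 3.06 and 2.61 against either wild type in the 10-array fit. At heat AT3G02480 and AT3G15670, of the same late embryogenesis family, were higher by at least log2 5.46 and 4.86 with all 12 arrays. The glutaredoxin gene AT2G47880 was lower in QK in both conditions, at 20.4 ± 1.63 against 146 ± 5.23 in Ws at control (SD, n = 2).

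In the 12-array fit 26 probe sets were higher and 1 lower in QK than in both wild types at control, and 133 higher and 5 lower at heat. BGLU19 had an adjusted p of 0.018 against Col-0 and 0.021 against Ws. In the 10-array fit the counts were 15 and 1 at control and 126 and 203 at heat (32, 6, 263 and 307 with the replicate block). ICL then had an adjusted p of 0.103 against Col-0 and 0.109 against Ws at control, AT1G04560 of 0.11 and 0.0994, and LEA18 of 0.0532 and 0.0441, so that these genes were no longer called against both. Of the genes named with 12 arrays, most that lost their call in the 10-array fit had it again with the replicate block. In the 10-array fit without the block the lower genes at heat were headed by HSP26.5 (-6.90), AT1G71000 (-6.67), HSP23.5 (-6.47), HSP15.7 (-6.21) and HOP3 (-6.09). Both comparisons share the QK arrays, and in 20 simulations of the 10-array fit with an unchanged QK the median count was 0 and the highest 1. The simulated QK lay midway between the wild types with independent noise. Replicate effects and differences between QK pools were not included, so the simulations do not bear on these. Of 5 late embryogenesis genes, a list added after the data were seen that was taken by gene symbol and holds LEA18 but not AT3G17520, AT3G02480 or AT3G15670, 1 was called higher at control and 3 at heat in the 10-array fit, with means of 2.25 and 2.91 and adjusted p = 0.366 and adjusted p = 0.249 with an estimated correlation. With 12 arrays the means were 2.09 and 2.85, with adjusted p = 0.146 and adjusted p = 0.0813. Limma then called 2 members higher at control and 2 at heat, and 3 and 3 with the replicate block. Levels in QK varied between replicates, as for ICL at control, 555.5 in replicate 1 and 2025.6 in replicate 2. Some of these genes varied in the wild types too, at low signal. AT3G02480 had 71.3 and 118.4 in the Col-0 arrays of replicate 2 and 9.8 and 12.1 in those of replicate 1. In Ws it had 23.7 and 55.9 in replicate 2 and 11.4 and 19.6 in replicate 1. ICL in Ws went the other way, and so did AT1G04560 in Ws at heat. With all 12 arrays the higher count at control lay between 2 and 60 as each array was left out, lowest without Ws control replicate 2 and highest without QK control replicate 1, and that at heat between 16 and 154, lowest without Ws heat replicate 1. As each Ws or QK array was left out of the 10-array fit, the higher count lay between 0 and 47 at control and between 48 and 147 at heat, and the lower count between 0 and 1 and between 124 and 174.

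**Figure D5:**
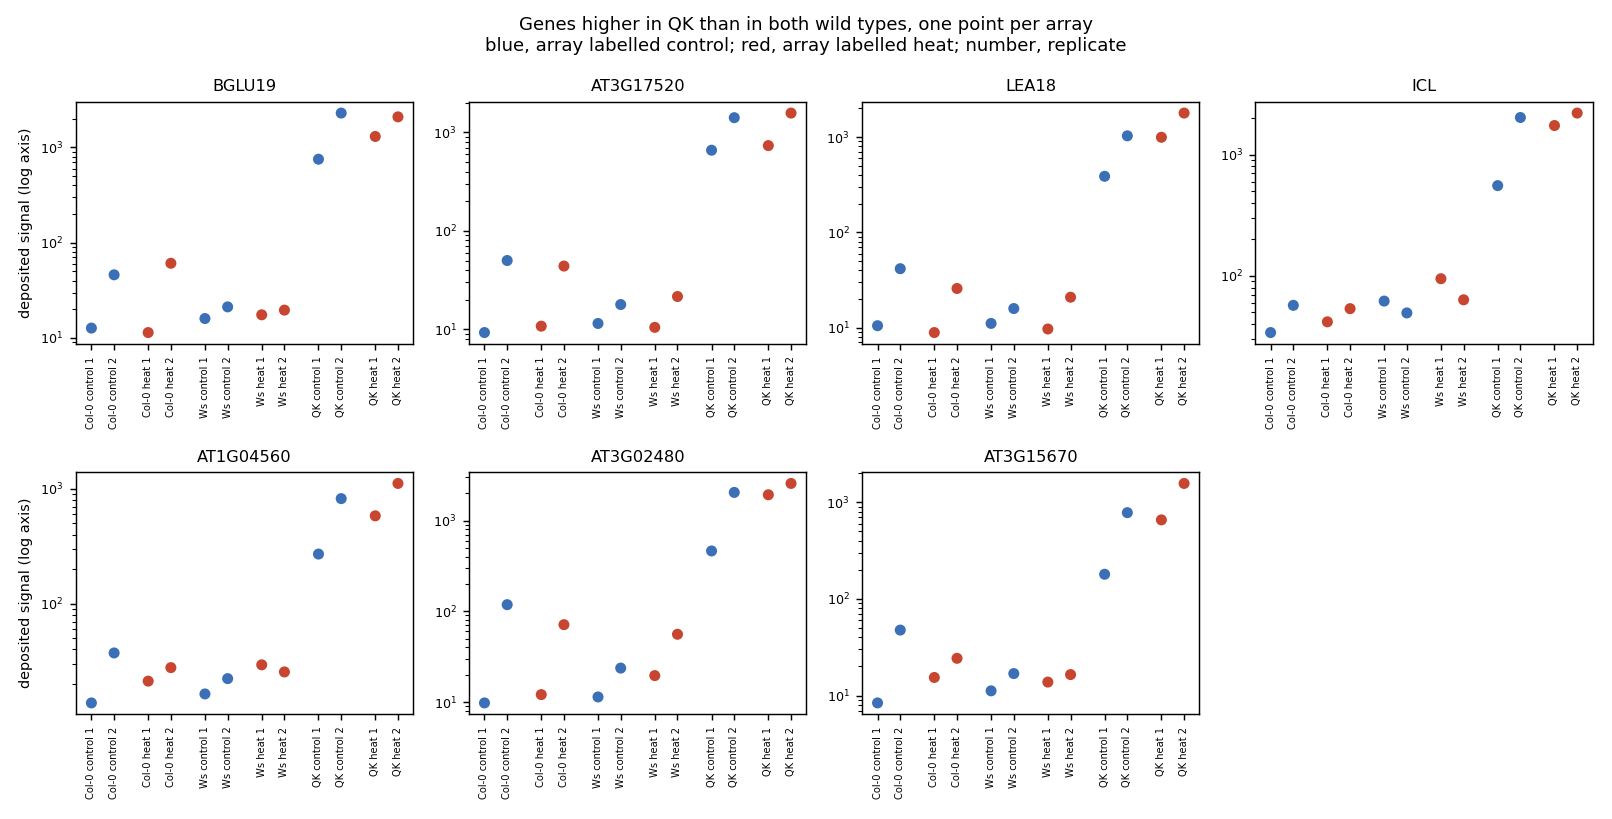
Deposited signal (log axis) of 7 genes higher in QK in each array, by labelled group (blue, control; red, heat). BGLU19 averaged 1520.5 in QK and 18.6 in Ws at control, and the arrays labelled Col-0 replicate 2 lay at 46.0 and 60.8.

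The auxin genes were lower as a set in QK at control in the 10-array fit, with a mean log2 of -0.82 against the wild types, 0 members called by limma and 2 when adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.4 with an estimated correlation; with 12 arrays adjusted p = 0.00259 and adjusted p = 0.236). GH3.3 was at 90.8 ± 14.9 in QK and 267 ± 46.5 in Ws (SD, n = 2). The photosynthesis genes had a mean of -0.24 (camera adjusted p = 0.0183, and adjusted p = 0.4 with an estimated correlation) and were not called with 12 arrays (adjusted p = 0.11). At heat the small heat shock proteins and co-chaperones were lower in QK with 7 and 5 members called and means of -5.13 and -3.40, and adjusted p = 0.215 and adjusted p = 0.12 with an estimated correlation. With 12 arrays the means were -3.46 and -2.57, with 0 members called by limma (camera adjusted p = 0.021 and adjusted p = 0.00361, and adjusted p = 0.657 and adjusted p = 0.642 with an estimated correlation). With the replicate block camera gave adjusted p = 0.0938 and adjusted p = 0.0199, so that the small heat shock proteins no longer passed. These means include the array labelled Col-0 heat replicate 2, which stood against its label. The endoplasmic reticulum genes were higher with 2 called, CRT1B and ERDJ3B, and a mean of 1.75, with adjusted p = 0.215 with an estimated correlation, and with 12 arrays a mean of 1.72 with adjusted p = 0.118. The 3 abscisic acid genes and the 4 cytosolic ribosomal protein genes were called as sets in 0 of the 6 contrasts with camera in either fit.

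Few probe sets were called different between Ws and Col-0 with all 12 arrays, where each Col-0 group holds an array of the pair labelled Col-0 replicate 2. At an unadjusted p under 0.05 limma gave 614 at control and 831 at heat, so the calls do not measure how many genes differ. ECS1, a cell wall protein, had a signal of 21.9 ± 14.8 in Ws at control (SD, n = 2) and between 1744.6 and 3556.4 in the 4 Col-0 arrays, a log2 difference of -6.11 with all 12 arrays (adjusted p = 0.0012). AT5G44580 differed by -3.14, AT3G47250 by -3.45, AT1G23960 by -2.97 and AT5G26270 by -2.52. Higher in Ws were AT1G50290 (3.87), AT2G15560 (9.86-fold) and AT5G02140 (2.15 at control and 0.25 at heat, where it was not called). HTB11, a histone H2B, differed by -3.54 in the 10-array fit and by -2.51 with an adjusted p of 0.43 with all 12 arrays. At control 3 probe sets were higher and 15 lower in Ws with all 12 arrays, and 29 differed in the 10-array fit (62 with the replicate block). At heat 30 and 48 differed (84 with the replicate block). With all 12 arrays the control count lay between 2 and 23 as each array was left out, lowest without either Ws control array, and the heat count between 5 and 43, lowest without Ws heat replicate 1. The probes of this array type were designed on Col-0 sequence, so that a lower signal in Ws also arises where its sequence differs.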

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

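All tests in this part were chosen after the result was seen, apart from the 12-array differences in heat response of single probe sets and of the endoplasmic reticulum and auxin lists. The results below differed between QK and the wild types in the test of the heat response itself. In the 12-array fit 1 probe set had a higher response in QK. As sets, with camera and the preset correlation, the endoplasmic reticulum genes differed by a mean of 1.57, the auxin genes by 1.08, the mitochondrial genes by 1.93 and the late embryogenesis genes by 0.76. With an estimated correlation camera gave adjusted p = 0.0613, adjusted p = 0.0966, adjusted p = 0.461 and adjusted p = 0.461. The mitochondrial value comes with the pair labelled Col-0 replicate 2, with which the mean change in Col-0 was -0.14, against 2.82 without it. In the 10-array fit 159 probe sets responded less and 21 more in QK. The lower ones were headed by HSP26.5 (-7.05), AT1G71000 (-6.73), HSP15.7 (-6.09), AT1G21550 (-5.68), HOP3 (-5.60) and AT5G25450 (-5.15). The higher ones were headed by XTH33 (2.58), AT4G37240 (2.47), AT5G44060 (2.41), AT4G35940 (2.35), UGT76B1 (2.29) and AT3G16330 (1.98). The list means were -4.97 for the small heat shock proteins, -3.05 for the co-chaperones, 1.55 for the endoplasmic reticulum genes, 1.06 for the auxin genes and 0.45 for the mitochondrial genes. With an estimated correlation none of these camera calls passed (adjusted p = 0.171, adjusted p = 0.0727, adjusted p = 0.178, adjusted p = 0.244 and adjusted p = 0.249).

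The heat genes of the pair labelled Col-0 replicate 2 stood against the treatment labels. A failed heat treatment is argued against by the heat index of 3.09 in the array labelled control, and an exchange with Ws by an accession index of at most 0.146 over 34 markers. An exchange of treatment labels within the pair is a candidate explanation, since 100% of 62 probe sets raised in Ws and QK lay higher in the array labelled control. Across tested probe sets, the array labelled Col-0 heat replicate 2 was most correlated with Ws control replicate 2 (r = 0.968). The array labelled Col-0 control replicate 2 was most correlated with Ws heat replicate 2 (r = 0.969). The exchange was proposed from these data, and the arrays were not regrouped.

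Small heat shock proteins gave a signal in QK heat replicate 2 that replicate 1 lacked, as with HSP17.6C (914.7 and 18.2). Heated Col-0 plants mixed into the sample are argued against as the only source. Of 7 probe sets bright in Col-0 and dim in Ws, 3 lay at or below 0.632% of the Col-0 signal. The median share of the small heat shock proteins was 4.91%. Heated Ws plants are argued against as the only source, if signal is proportional to RNA over this range, which was not tested. The highest share of the Ws rise (HSP22 9.63%) was 8.04 times the lowest. The ratio of the rises in the Ws replicates spread over 1.56 times among these genes. A mixture beside a response of the QK plants would also give unequal shares. A partial response in part of the plants may remain and was not tested. A background that differs between the seedling pools may also remain, since the marker test for it found 0 shared neighbouring pairs among too few differing markers to decide.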

How the results depend on the processing

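The fits with 10 arrays and their alternatives were chosen after the data were seen, and all other alternatives were planned. Signal over background limits the dim genes, and 2 arrays per group limit the rest. Scaling on hybridisation controls was not run, since the table holds 0 such probe sets. No result changed direction while called. Of 288 list results 247 stayed on their side of the threshold, 16 passed it anew and 25 no longer passed it. Of 725 values of genes named with 12 arrays 525 held their call and 200 lost it, and of 700 with 10 arrays 510 held it and 190 lost it. Unless the setting itself removes arrays or probe sets, the cause was not tested.

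With the replicate block in the 12-array fit, 69 probe sets were raised and 3 lowered by heat in QK, and 7 had a higher response in QK. Against both wild types 44 were higher and 6 lower in QK at control, and 225 higher and 22 lower at heat. Between Ws and Col-0 41 and 55 differed at control and heat, and 5 differed in their response. Camera lost 2 list calls, the root markers in heated QK (adjusted p = 0.0689) and the small heat shock proteins of QK against the wild types at heat (adjusted p = 0.0938). With the block in the 10-array fit the counts were 392 raised and 444 lowered in Col-0, 549 and 570 in Ws, 273 and 451 in QK, 280 with a lower and 95 with a higher response in QK, 32 higher and 6 lower in QK at control, 263 and 307 at heat, 62 and 84 different between Ws and Col-0 at control and heat, and 21 list tests passed.

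The 10-array fit against the 12-array fit gave 217 raised and 58 lowered in Col-0, 471 and 276 in Ws, 160 and 189 in QK, 159 with a lower and 21 with a higher response in QK, 15 higher in QK at control, 203 lower at heat, 29 and 48 different between Ws and Col-0, and 20 of 48 list tests passed against 13. An estimated correlation left 0 list tests and fry 4.

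The lowered count in QK (1) was 0 with quantile normalization, 2 when centred on the 75th percentile, 0 with a pseudocount of 1 or 64, without the filter, with the filter at the 50th percentile, without the variance trend and at 4-fold or more. Quantile normalization gave 27 lowered in Col-0 in the 10-array fit. A pseudocount of 1 gave 5 raised in Ws, 15 raised in QK and 0 with a higher response in QK. A pseudocount of 64 gave 1 lowered in Ws, 1 with a lower and 5 with a higher response in QK, 2 lower in QK at heat and 5 responses different between Ws and Col-0. Without the filter 1 was lowered in Ws, 3 had a higher response in QK and 2 responses differed between Ws and Col-0. With the filter at the 50th percentile 5 were raised in Ws, 16 raised in QK and 0 had a higher response. At 4-fold or more 22 were raised in QK, and 79 were higher and 1 lower in QK at heat. The 4 arrays of 1 genotype gave 319 raised and 100 lowered in Ws and 5 lowered in QK. Against Col-0 alone 27 were lower in QK at control and 41 at heat. Against Ws alone 0 had a higher response, 3 were lower at control and 55 lower at heat, and in the 10-array fit 13 had a higher response, 3 were lower at control, and 265 were higher and 368 lower at heat.

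With each array left out of the 12-array fit in turn, the raised counts were 0 to 14 in Ws and 0 to 26 in QK, and the lowered counts 0 to 1 in Ws and 0 to 2 in QK. The responses in QK were lower for 0 to 2 and higher for 0 to 6. QK was higher for 2 to 60 at control and 16 to 154 at heat, and lower for 0 to 3 and 0 to 13. Ws and Col-0 differed for 2 to 23 at control and 5 to 43 at heat, and 8 to 28 of 33 named genes were called. With each Ws or QK array left out of the 10-array fit the raised counts were 161 to 185 in Col-0, 258 to 453 in Ws and 55 to 138 in QK, and the lowered counts 6 to 22, 29 to 258 and 8 to 132. The responses in QK were lower for 58 to 123 and higher for 2 to 11. QK was higher for 0 to 47 at control and 48 to 147 at heat, and lower for 0 to 1 and 124 to 174. Ws and Col-0 differed for 5 to 23 at control and 13 to 33 at heat.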

Other observations

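All tests in this part were chosen after the result was seen. Among lists with 1 or 2 measured genes, the defence regulator WRKY53 had a signal of 287.1 and 288.3 in the QK heat arrays and 12.3 to 114.9 in the other 10 arrays, and its log2 change on heat in QK of 2.45 missed the threshold in the 10-array fit (adjusted p = 0.137). ZAT10, a zinc finger regulator of stress genes, went from 166 ± 104 to 844 ± 72.1 in Ws and from 692 ± 633 to 412 ± 108 in QK (SD, n = 2), and neither change was called. In the same fit the log2 changes on heat in Ws were 0.65 for BZIP28, a membrane-bound regulator of the folding response, 0.18 for the defensin PDF1.2 and -0.26 for MCM7 and 0.26 for AUR1 of the cell cycle. They were -0.40 for the clock gene GI, 0.26 for BCAT4 and -0.27 for UGT74B1 of glucosinolate synthesis, and 0.12 and -0.23 for the reference genes TIP41 and SAND.

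A plastid-genome RNA, atpA for a subunit of the ATP synthase, differed widely between replicates, with signals of 313.0 and 1662.6 in the QK control arrays and 332.6 and 2992.2 in the QK heat arrays. Over 66 plastid genes the mean log2 change on heat was -0.07 in Ws and -0.05 in QK in the 10-array fit, with 0 called by limma.

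QK carried both accession states at genes that differ between Ws and Col-0. Of 92 markers, 47 were nearer the Ws level and 21 nearer the Col-0 level in all 4 QK arrays, and 24 differed among them. The split lay midway between the accession means on the log2 scale, so that values near the middle or outside both are counted too. On an index of 0 for Col-0 and 1 for Ws, AT1G67860 in QK heat replicate 2 was at 0.518. ECS1 was at the Col-0 level and AT3G47250 at the Ws level in each QK array. A mixture of Col-0 plants is argued against, since each QK array held at least 3 of 7 markers under 5% of the Col-0 signal beside others above 50%. Blocks of chromosome from both accessions are a candidate explanation, since 27 of 45 neighbouring pairs shared a pattern where the median of permutations was 17 (one-sided permutation p = 3e-05, 100000 permutations). Single markers switched fully between QK arrays. JAL33 was at 0.588% of the Col-0 signal in QK control replicate 1 and at 70.7% to 145% in the other QK arrays, and AT1G73490 was at -0.370% in QK heat replicate 1 and at 85.4% to 99.8% in the others. The accession index was 0.968 and 0.976 in the QK arrays of replicate 1, from which its 34 markers were chosen in the wild types, and 0.684 and 0.660 in those of replicate 2. Of the 92 markers, 12 differed in state between the QK control arrays and 9 between the QK heat arrays. Between control and heat 16 differed in replicate 1 and 11 in replicate 2, so the states did not divide by replicate alone. Whether these differences form blocks that differ between the seedling pools was left undecided by the test, since 11 of the 50 ordered markers differed among the QK arrays and 0 pairs of them were neighbours with a shared pattern.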
